A study of Homo sapiens with 6 samples.

How the data were processed

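Gene expression was measured in a human colorectal cancer cell line, which the labels do not name, on 6 Agilent 1-colour oligonucleotide arrays. Per the labels, 3 arrays held RNA of cells infected with an empty control lentivirus and 3 held RNA of cells infected with a lentivirus carrying eGFP and a short hairpin RNA against SEMA3F, with eGFP-positive cells enriched by flow cytometry. RNA was amplified and labelled with Cy3, per the labels' protocols. The series' design text speaks of independent experiments but does not say whether each arm was sorted more than once.

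The deposited scanner files hold the intensity of each spot on a linear scale, written by Agilent Feature Extraction, per the file headers and the submitters' processing notes, which name version 10.7. The processed intensity was background-subtracted and spatially detrended by that software, per the file headers, with no normalization between arrays. Each file held 45015 spots, of which 43376 were not control spots and represented 41000 probes. The deposited table of the authors' values was on the log2 scale. Each of its columns had a median of 7.81 and correlated across probes with its own array's log2 intensity at 0.999 to 1.00, which settled its scale. Its sorted values differed between columns by a median of 0.00044 and at most 0.045, so it was taken as quantile normalized between arrays, which the labels do not state.

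The main values were log2 of the processed intensity minus each array's 75th percentile over non-control spots. Control spots and spots with a feature outlier flag were left out, and the spots of a probe were averaged. A probe entered if it was well above background on at least 3 of the 6 arrays and had at least 2 values in each group, which left 29299 probes by the first of these criteria. A probe counted as well above background on an array where at least 0.5 of its spots carried that flag. The files give accessions, not symbols, so probes were named through a RefSeq table (assembly GRCh38.p14) by unversioned accession. A symbol was found for 26222 of the 41000 probes (64.0%), and other probes kept the name in the file. The array annotation is on GRCh37, so no coordinates are given, and the table served for names and gene order only. Of the probes of a gene, the brightest over all arrays was used, which left 22330 genes, 13956 of them with a symbol.

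Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Changes are knockdown minus control on the log2 scale, with the fitted standard error (SE), and n = 3 arrays per group in the main comparison. A fit without 1 array has 2 arrays against 3. Calls with an absolute log2 change of at least 1 were also counted. A gene not well above background on any array of a group has only a bound there. Its fold is then given as at least the bright group's mean over the dim group's mean, each dim array being set to the higher of its lowest well-above-background signal and the probe's own. For 1 probe at a time an exact permutation test was used. With 3 arrays against 3 its smallest two-sided p is 0.1.

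Before the data were examined, 22 gene lists, the design, the alternatives and the rule for named genes were fixed. The rule names SEMA3F, ASCL2 and CXCR4, then the 12 largest rises and 12 largest falls past the threshold that had a gene symbol, no overlap between the groups and signal well above background on all 3 arrays of a group, then up to 4 members of each list past the threshold by smallest adjusted p, or 2 by size of change. Genes named outside this rule (VIM, TWIST1, ACTA2, CDKN1A, AEN, BCL2L11, KLF4 and the FOXO genes in the comparison) were chosen after their values were seen. Some genes that the rule names are not reported here. Lists were tested with limma's camera with a preset correlation of 0.01, two-sided, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether members move one way on balance without comparing them with other genes. Members were counted with p adjusted over all genes and adjusted over the list alone.

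The arrays came from 3 slides. Slide 1 held control 1, slide 2 held control 2, control 3 and knockdown 1, and slide 3 held knockdown 2 and 3. Control 1 was also scanned on another day than the other arrays. Slide entered as a fixed block, as a random block, and through slide 2 alone. With slide as a fixed block, the group effect rests on slide 2, because the other slides hold 1 group each. Slide 2 alone is 1 knockdown array against 2 control arrays, so its spread comes from the 2 controls, moderated across genes, and the lone knockdown array is assumed to vary like them. The fixed block and slide 2 alone are therefore not independent of each other. Leaving out control 1 gives the comparison within 1 scan day.

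Alternatives also covered background correction, between-array normalization, the authors' value table, the filter on dim probes, flagged spots, the choice of probe, the variance model, array weights, the replicate number as a block and each array left out. The planned normexp correction (offset 50) was to use the mean spot signal, but the files used here have the median spot signal, which took its place. After the data were seen, 2 alternatives were added: scaling on the E1A spike-in controls, and normexp without spots that carry a background outlier flag.

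On simulated data with the measured means and residual spreads of the 22330 genes, 200 genes were changed by known amounts. Of those changed by 0.5, 1 and 2 on the log2 scale, 41.8%, 73.1% and 89.4% were called, and 9 unchanged genes were called. Of 22 simulated lists of 20 genes, both shifted lists were called in the right direction and 0 of the others. Genes were simulated independently, so list members were not correlated. In the data the estimated correlation was 0.17 for FOXO targets, 0.062 for mesenchymal genes and 0.075 for p53 targets. The simulation therefore cannot show how often camera calls an unshifted list of correlated genes. The shares called rest on 200 changed genes, far fewer than were called in the data.

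Between 67.8% and 75.1% of probes were well above background on each array, and 0 spots were saturated. Over 209 probes with repeated spots, the median SE of a probe's mean from its spots was 0.027, and the median SD between arrays of a group was 0.059 on the log2 scale. The number of arrays limits the precision.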

Results

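The transcriptome of a human colorectal cancer cell line was compared between cells carrying a lentivirus with a short hairpin RNA against SEMA3F (knockdown, n = 3 arrays) and cells carrying an empty lentivirus (control, n = 3 arrays). SEMA3F is a secreted class 3 semaphorin that signals through neuropilin-2 and plexins. The 75th percentile of signal lay between 1790 and 2259 units per array. Levels below are log2 signals relative to that percentile, and changes are knockdown minus control. The arrays of a group correlated with one another across genes at 0.992 to 0.995, and arrays of different groups at 0.971 to 0.978. The lowest correlation within a group exceeded the highest between groups by 0.0140. The first principal component held 68.5% of the variance and separated the groups. The p-values measure only the spread between these samples, which may be technical.

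The first question was whether the targeted transcript was lower in the knockdown cells. SEMA3F was at -4.16 ± 0.017 (SD, n = 3) in control and -5.18 ± 0.14 (SD, n = 3) in knockdown cells, 2.03-fold lower (log2 change -1.02, SE 0.082, limma adjusted p = 0.000305). Its signal was 49.3% of control by the brighter probe, A_24_P300076, and 64.6% by the second probe, A_23_P6878. Each probe was lower on all 3 knockdown arrays than on any control array, and the exact two-sided permutation p was 0.1 for each, the smallest that this design allows. CXCR4, the receptor of the chemokine CXCL12, fell by 1.65 (SE 0.11, 3.13-fold lower, limma adjusted p = 0.000147). ASCL2, a transcription factor of intestinal stem cells, had 2 probes on the array. The first was well above background on 0 control arrays and 1 knockdown array, and the second on none of the 6, so that its change was not measurable. With slide as a fixed block the change was -0.92 for SEMA3F (adjusted p = 0.0151) and -1.43 for CXCR4 (adjusted p = 0.00747). Within slide 2 alone, 1 knockdown array against 2 control arrays, the estimates were the same and had adjusted p = 0.0421 and 0.0414, which rest on the spread of the 2 control arrays.

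**Figure D1:**
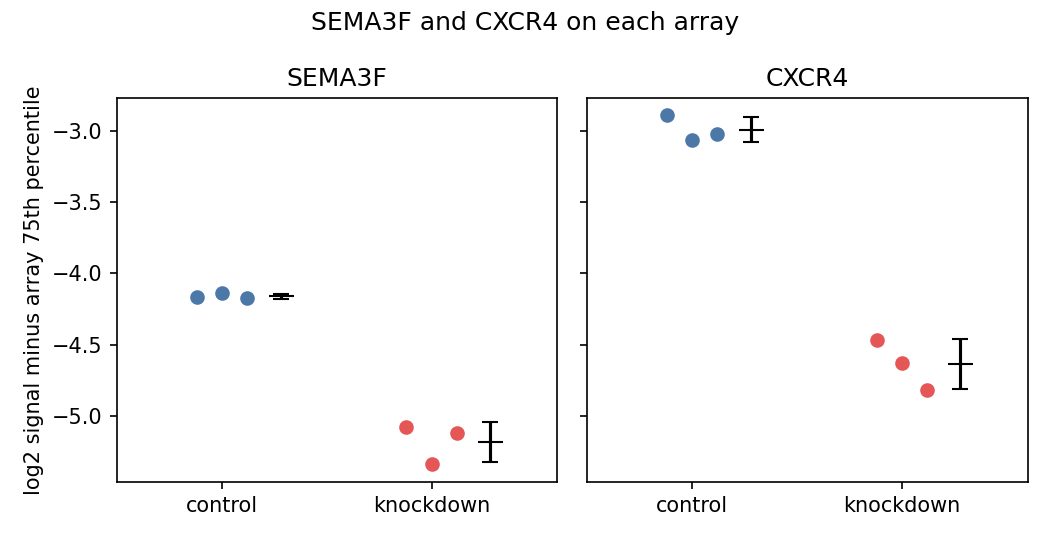
Log2 signal relative to each array's 75th percentile for SEMA3F (left) and CXCR4 (right), by group. Points are the 3 arrays of a group and bars the mean ± SD. SEMA3F averaged -4.16 in control and -5.18 in knockdown cells, and CXCR4 -2.99 and -4.64, with no overlap between the groups.

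The second question was how far the rest of the transcriptome differed. Of 22330 genes tested, 10465 (46.9%) passed the threshold, 5049 higher and 5416 lower in knockdown cells. Among these, 2014 changed by at least 1 on the log2 scale, 657 higher and 1357 lower, and 4553 changed by less than 0.5. The groups did not overlap for 12960 genes (58.0%), where chance gives 10%. Called genes included 60 that were well above background on no control array and 63 on no knockdown array. Of 2872 called genes with more than 1 probe, 2447 (85.2%) had all probes changing in the same direction. With slide as a fixed block 7215 genes were called, and within slide 2 alone, with its 1 knockdown array, 2817. The split between directions depended on the scaling: 48.2% of called genes were higher with the 75th percentile, 62.8% with median centring and 25.5% with the E1A spike-in controls, a scaling chosen after seeing the data. The median change of all genes was 0.024, 0.14 and -0.16 under these scalings, so small changes have a direction only relative to the scaling.

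The largest fitted rise was in FGF1, a fibroblast growth factor. It rose by 5.13 (SE 0.40, adjusted p = 0.000266), and was well above background on 1 of 3 control arrays. TGFBI, an extracellular matrix protein, was at least 9.63-fold higher (adjusted p = 2.8e-05), and CCN4, a secreted matricellular protein, at least 3.19-fold higher (adjusted p = 0.000119), neither being above background on any control array. The smooth muscle genes CNN1 (calponin) and ACTG2 (an actin) rose by 4.79 (SE 0.087) and 4.12 (SE 0.14), with CNN1 above background on 2 control arrays. MYPN, a sarcomere protein, rose by 3.88 (SE 0.44), and by 4.53 with slide as a fixed block. KRT80, an epithelial keratin, rose by 4.21 (SE 0.090), and by 2.52 as the mean of its probes. CPA4, a carboxypeptidase, rose by 3.77 (SE 0.071) and MPO, the peroxidase of neutrophil granules, by 3.84 (SE 0.15). MYPN and MPO were above background on 1 control array each. MAB21L4 was at least 7.80-fold and TM4SF18 at least 6.24-fold higher, from no control array above background. TM4SF18 varied most among the knockdown arrays of these 12 genes (SD 1.61). Without knockdown 2 its change was 2.80 and its bound 3.29-fold, and it did not pass with slide as a fixed block (2.87, adjusted p = 0.175).

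The largest fitted fall was in CXXC4, an inhibitor of WNT signalling. It fell by 3.83 (SE 0.20, adjusted p = 8.4e-05), with 2 of 3 knockdown arrays above background. RECK, a membrane-anchored inhibitor of matrix metalloproteinases, fell by 3.51 (SE 0.12, adjusted p = 4.5e-05). ARID5B, a DNA-binding protein, fell by 3.11 (SE 0.061), with 4 of 4 probes lower. APOLD1 fell by 3.45 (SE 0.085) and KLHL24 by 3.29 (SE 0.25). BMF, a pro-apoptotic BCL2 family member, fell by 3.31 (SE 0.50), with 1 knockdown array above background, and by 2.18 with slide as a fixed block and within slide 2. PSD2 was at least 3.43-fold lower, the potassium channel gene KCNN3 at least 2.92-fold, BTN3A3 at least 5.38-fold, the glucose transporter gene SLC2A12 at least 4.36-fold and SRGAP3 at least 3.05-fold, none being above background on a knockdown array. TMEM150C fell by 3.26 (SE 1.01, adjusted p = 0.042) with 2 of 3 knockdown arrays above background, but its control arrays spread widely (SD 2.03), and without control 2 the change was -2.09. It did not pass with slide as a fixed block (adjusted p = 0.194) or without any one of the knockdown arrays (adjusted p from 0.0769 to 0.118). Of the 24 genes of largest change, 22 passed with slide as a fixed block and 21 within slide 2.

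**Figure D2:**
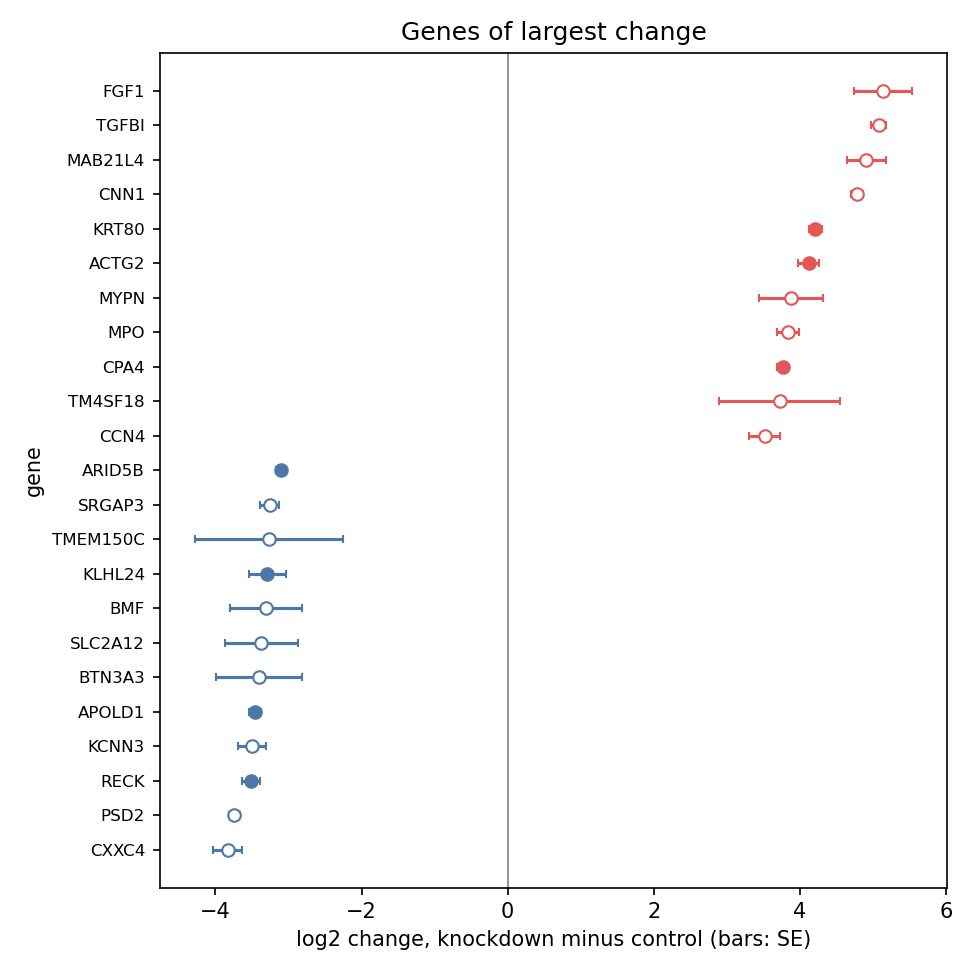
Log2 change, knockdown minus control, of 11 of the 12 largest rises (red) and the 12 largest falls (blue), with bars for the fitted SE. Filled points were well above background on all 6 arrays, and open points on fewer, so that their size is less certain. Rises lie between 3.52 (CCN4) and 5.13 (FGF1), and falls between -3.83 (CXXC4) and -3.11 (ARID5B).

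Of the 22 gene lists, 3 passed the threshold. The clearest was the list of genes that AKT signalling represses through FOXO transcription factors. Of 19 members tested, 15 fell and 3 rose, with a median change of -1.05 (camera adjusted p = 7.41e-05). Adjusted over the list alone, 18 passed. CCNG2, a cyclin, fell by 2.44 (SE 0.058), SESN3, a stress-response sestrin above background on 1 of 3 knockdown arrays, by 2.23 (SE 0.084), YPEL3 by 1.99 (SE 0.071) and BCL6, a transcriptional repressor, by 1.90 (SE 0.080). The members that rose were BCL2L11 (0.46, 3 of 4 probes), a pro-apoptotic gene, KLF4 (0.54), an epithelial transcription factor, and FOXO3. FOXO1 fell by 1.13 and FOXO4 by 0.88, while FOXO3 rose by 0.36, all 3 being FOXO factors themselves. The call was lost with an estimated correlation (adjusted p = 0.499 with an estimated correlation). The median was -0.96 with slide as a fixed block (adjusted p = 0.000665) and -0.99 within slide 2 (adjusted p = 0.000293), both resting on knockdown 1 and the controls beside it.

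Mesenchymal genes of epithelial-mesenchymal transition were higher as a list, with a median of 0.65 over 19 members (camera adjusted p = 0.0456). The median was 0.22 with no filter on dim probes and 0.42 with the filter on all 6 arrays. Of these, 11 rose and 5 fell, and 16 passed adjusted over the list alone. TAGLN, a smooth muscle actin-binding protein, rose by 2.18 (SE 0.056), and the matricellular genes CCN1 and CCN2 by 2.11 (SE 0.077) and 2.24 (SE 0.093), beside TGFBI. In contrast, VIM fell by 0.45, TWIST1 by 0.86 and ACTA2 by 0.34. The call was lost with an estimated correlation (adjusted p = 0.499 with an estimated correlation) and in 9 of 22 other settings (adjusted p up to 0.314), median centring among them (adjusted p = 0.0682). The median was 0.63 with slide as a fixed block (adjusted p = 0.0301) and within slide 2 (adjusted p = 0.0361), which is the same comparison of 3 arrays.

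Targets of p53 were lower as a list, with a median of -0.30 over 22 members (camera adjusted p = 0.0456). Of these, 11 fell, 1 rose and 10 did not pass, and 13 passed adjusted over the list alone. TP53INP1 fell by 1.81 (SE 0.053), GDF15, a stress-induced cytokine, by 1.66 (SE 0.068), BTG2, an antiproliferative gene, by 1.52 (SE 0.074) and RRM2B, a ribonucleotide reductase subunit, by 0.80 (SE 0.050). The cell cycle inhibitor CDKN1A fell by 0.84. AEN, an apoptosis-enhancing nuclease, rose by 1.01. The call was lost with an estimated correlation (adjusted p = 0.499 with an estimated correlation) and in 6 of 22 other settings. The median was -0.18 with median centring and -0.49 with spike-in scaling. It was -0.29 with slide as a fixed block (adjusted p = 0.0199) and -0.32 within slide 2 (adjusted p = 0.0339). Without knockdown 1 the mesenchymal and p53 lists did not pass (adjusted p = 0.10 for both). Without knockdown 2 they did not pass either (adjusted p = 0.0598 and 0.0537), and without control 3 the p53 list did not (adjusted p = 0.0692). The p53 list also did not pass with array weights (adjusted p = 0.0813), the replicate number as a block (adjusted p = 0.0618) or the filter on all 6 arrays (adjusted p = 0.0525).

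**Figure D3:**
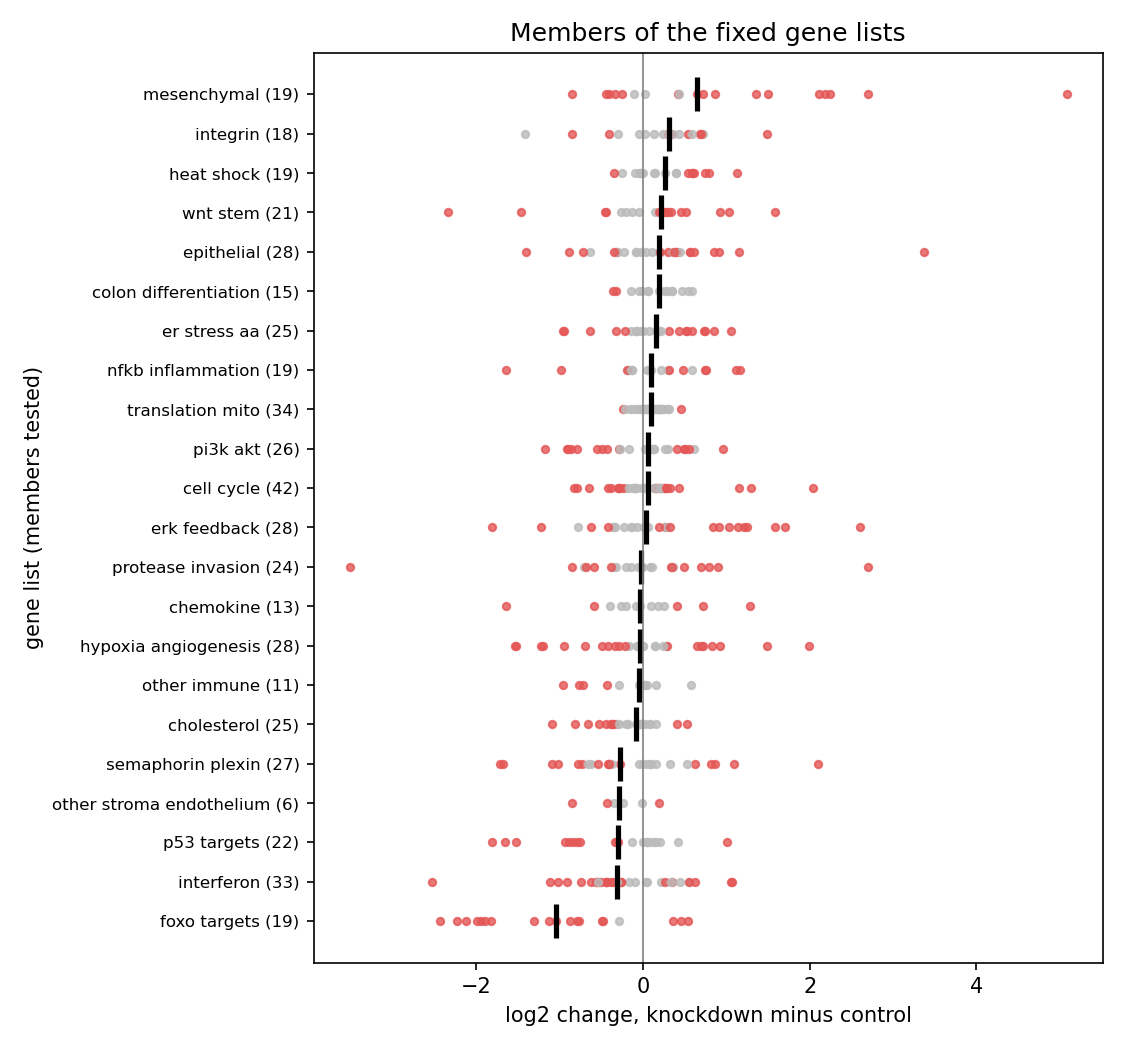
Log2 change, knockdown minus control, of each tested member of the 22 gene lists. Red points passed the threshold over all genes, grey points did not, and black bars are list medians. Medians run from -1.05 for FOXO targets to 0.65 for mesenchymal genes.

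The other lists did not pass as lists, though many members changed. Among semaphorins, neuropilins and plexins, 5 of 27 rose, 11 fell and 11 did not pass (median -0.28, camera adjusted p = 0.479), and 17 passed adjusted over the list alone. Without knockdown 1 the median was -0.027. SEMA7A, SEMA3A and SEMA3C rose by 2.10, 1.09 and 0.81, whereas SEMA3E fell by 0.77. Of 21 WNT target and intestinal stem cell genes, 11 rose and 4 fell (median 0.22, adjusted p = 0.254), and 16 passed adjusted over the list alone. Their median ran from 0.033 to 0.33 in 22 other settings. CCND1 rose by 1.59, MYC by 1.04 and DKK1 by 0.93, and the ephrin receptor gene EPHB3 fell by 1.47. Of 28 immediate early and feedback genes of ERK signalling, 12 rose and 4 fell (median 0.037, adjusted p = 0.368), and 20 passed adjusted over the list alone. FOSL1 rose by 2.60 and the phosphatase gene DUSP4 by 1.71, while the transcription factor gene ETV5 fell by 1.81. Of 13 chemokine and receptor genes, 3 rose and 2 fell (median -0.033, adjusted p = 0.953), and 4 passed adjusted over the list alone. Beside CXCR4, CCR7 fell by 0.58, and CXCL2 rose by 0.41 and CXCR3 by 1.29, with CCR7 above background on 2 control arrays and 1 knockdown array and CXCR3 on 1 control array. CXCR3 did not pass without control 2, control 3, knockdown 1 or knockdown 2 (adjusted p from 0.0522 to 0.0544). With slide as a fixed block CCR7 and CXCL2 did not pass (adjusted p = 0.0918 and 0.0534).

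Of 28 epithelial junction and keratin genes, 12 rose and 5 fell (median 0.20, adjusted p = 0.412), and 22 passed adjusted over the list alone. The median of these genes ran from 0.015 to 0.37 in 22 other settings. The tight junction gene TJP1 rose by 1.15 and the protease gene ST14 by 0.91, while the claudin CLDN3 fell by 0.88 and GRHL2 by 0.72. The probes of CLDN3 disagreed, 1 of 2 being lower, and their mean did not pass (-0.082, adjusted p = 0.458). Of 18 integrin subunits, 6 rose and 2 fell (median 0.32, adjusted p = 0.185), and 7 passed adjusted over the list alone, with ITGA2 up by 1.49, ITGB1 by 0.70, ITGA3 by 0.69 and ITGA6 by 0.54. Of 24 matrix protease and inhibitor genes, 7 rose and 5 fell (median -0.020, adjusted p = 0.919), and 17 passed adjusted over the list alone. The plasminogen activator PLAU rose by 0.90, and MMP11 fell by 0.85. Of 15 genes of differentiated colon epithelium, 0 rose and 2 fell, against a median of 0.20 over all members (adjusted p = 0.739), and 1 passed adjusted over the list alone. That median was -0.078 without knockdown 2 and -0.056 with slide as a fixed block. CA2 fell by 0.36 and DPP4 by 0.33, the latter with adjusted p = 0.050. DPP4 did not pass without control 1, control 2, knockdown 2 or knockdown 3 (adjusted p from 0.117 to 0.135), and was at -0.13 with slide as a fixed block (adjusted p = 0.514).

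Of 26 components of the PI3K-AKT-mTOR pathway, 5 rose and 9 fell, and 14 passed adjusted over the list alone. Its median was 0.061 and its mean -0.082, and camera's direction was down (adjusted p = 0.704), so that these differ in sign. RICTOR fell by 0.79, PIK3CA by 0.90 and PIK3CD by 1.18, and the phosphatase PHLPP2 rose by 0.96. Of 42 genes of DNA replication and mitosis, 13 rose, 9 fell and 20 did not pass (median 0.055, adjusted p = 0.440), and 25 passed adjusted over the list alone. The cyclins CCNE1 and CCNE2 rose by 1.15 and 2.04 and CDC25A by 1.29, while the mitotic kinesin KIF20A fell by 0.79. Of 28 hypoxia and angiogenesis genes, 8 rose and 11 fell (median -0.035, adjusted p = 0.761), and 20 passed adjusted over the list alone. SLC2A1 and HK2, of glucose uptake and glycolysis, rose by 1.49 and 0.83, and EGLN3 and KDM3A fell by 1.53 and 1.20.

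Of 33 interferon-stimulated genes, 6 rose and 17 fell (median -0.32, adjusted p = 0.136), and 25 passed adjusted over the list alone. IFIT1 fell by 2.52, IFIH1 by 1.12 and IRF9 by 1.02, while OASL rose by 1.06. Of 19 NF-kB targets, 6 rose and 3 fell (median 0.096, adjusted p = 0.473), and 9 passed adjusted over the list alone. IL18 rose by 1.12 and RELB by 1.17, and C3 fell by 0.98 and PTGS2 by 1.65, the latter above background on 1 knockdown array. Of 25 unfolded protein response and ATF4 targets, 9 rose and 5 fell (median 0.15, adjusted p = 0.317), and 15 passed adjusted over the list alone. SLC7A5, PPP1R15A and XBP1 rose by 1.06, 0.86 and 0.74, and ATF3 fell by 0.96. Of 19 heat shock and handling stress genes, 7 rose and 1 fell (median 0.26, adjusted p = 0.123), and 8 passed adjusted over the list alone, with HMOX1 up by 1.13, MT1E by 0.79, DNAJA1 by 0.61 and MT1G by 0.58. Of 25 cholesterol synthesis genes, 2 rose and 8 fell (median -0.088, adjusted p = 0.276), and 10 passed adjusted over the list alone. HSD17B7 and INSIG1 fell by 0.81 and 0.53, and HMGCS1 rose by 0.53. Of 34 ribosomal and respiratory chain genes, 2 rose and 1 fell (median 0.094, adjusted p = 0.317), and 0 passed adjusted over the list alone by limma. CYCS rose by 0.45 and RPL13 by 0.22, and SDHA fell by 0.24. RPL13 did not pass without control 1, control 3, knockdown 2 or knockdown 3 (adjusted p from 0.122 to 0.141), nor SDHA without control 2, control 3 or knockdown 3 (adjusted p from 0.0630 to 0.0704). With slide as a fixed block RPL13 was at 0.13 (adjusted p = 0.404) and SDHA at -0.29 (adjusted p = 0.0514), and neither passed. Between the scalings by the 75th percentile, median centring and spike-in controls, the medians of 11 uncalled lists differed in sign: chemokines, PI3K-AKT-mTOR, replication and mitosis, hypoxia, matrix proteases, ERK feedback, NF-kB, the unfolded protein response, cholesterol synthesis, ribosome and respiration, and immune markers. With slide as a fixed block the chemokine median was 0.15 and the PI3K-AKT-mTOR median -0.018, also of the other sign, while the integrin median was 0.14 and the heat shock median 0.036. With fry, 13 of the 22 lists passed, and with an estimated correlation 0 did, the lowest adjusted p being 0.499.

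Markers of other cells were examined because a sorted tumour cell line should lack them. Of 20 blood and immune markers, 11 were well above background on all arrays of each group. The others, PTPRC, CD3D, MS4A1, LYZ, FCGR3A, GNLY, HBB, LCP2 and LAPTM5, were above background on no array. CD3E and HBA1 were thus above background without CD3D and HBB, so the flag alone does not show that blood or immune cells were present. Of the 11 tested, 0 rose and 4 fell (median -0.049, adjusted p = 0.317), and 4 passed adjusted over the list alone. CSF1R went from -2.68 in control to -3.45 in knockdown cells, CD8A from -2.19 to -3.15 and HBA1 from -1.02 to -1.45. Of 18 fibroblast and endothelial markers, 6 were well above background on all control and 5 on all knockdown arrays. Of the 6 tested, 1 rose and 2 fell (median -0.29, adjusted p = 0.465), and 3 passed adjusted over the list alone. THY1 went from 1.40 to 1.59, RGS5 from -2.58 to -3.02 and PDGFRB from -5.39 to -6.24, the last being above background on 1 knockdown array. THY1 did not pass without any one array except control 3 (adjusted p from 0.0806 to 0.125) or with slide as a fixed block (0.15, adjusted p = 0.242), nor RGS5 without any one except control 2 (adjusted p from 0.0504 to 0.0934).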

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

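A control-type probe outside the main comparison, named AT_ssH_AB_5 in the files, was brighter in the knockdown cells than in the controls. Its log2 signal was 2.98 ± 0.13 (SD, n = 3) in control and 4.27 ± 0.093 (SD, n = 3) in knockdown arrays, a difference of 1.29 (limma adjusted p = 0.000185 over 35 control-type probes). Of the 35 probes 4 passed, the others being AT_ssH_AB_3 (0.53, adjusted p = 0.00531), AT_ssH_TR_3 (0.42, adjusted p = 0.0178) and AT_ssH_TR_5 (0.48, adjusted p = 0.0178). The probe was singled out after the control-type probes had been looked at. The files do not pair these names with genes. The 8 E1A spike-in probes above background on all arrays differed by 0.15 to 0.23, with a median of 0.18.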

How the results depend on the processing

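The scaling on spike-in controls and normexp without background outliers were chosen after seeing the data. The planned normexp correction failed on knockdown 1. There, 8 spots, all with a background outlier flag, lay more than 100 units below their local background, the lowest by -27349.5, and the array's 10th percentile after correction was 875.9 against 64.5 to 70.5 on the others. Its values therefore describe that fit: 1167 genes called, 702 higher and 465 lower, SEMA3F 0.32, CXCR4 -0.34, 7 lists past the threshold, and the lowest correlation within a group lying below the highest between groups (-0.0192). Under it 13 named genes changed sign: PSD2 0.15, KCNN3 0.39, SLC2A12 0.20, SRGAP3 0.34, SEMA3E 0.26, CCR7 0.86, DPP4 0.47, SESN3 0.22, C3 0.14, PTGS2 0.53, RPL13 -0.050, PDGFRB 0.75 and RGS5 0.14. Of the lists called in 1 of the 2 settings, those of DNA replication and mitosis (median -0.057) and of ribosomal and respiratory chain genes (-0.060) did so too. Among lists called in neither, medians below 0 in the main setting also turned positive. These included semaphorins, neuropilins and plexins (0.47), chemokines (0.78), hypoxia (0.11) and fibroblast and endothelial markers (0.26). Without the flagged spots, normexp gave a 10th percentile of 66.4 on that array and called 9939 genes, 9360 of them also called in the same direction by the main setting, with SEMA3F -0.51, CXCR4 -1.07 and 3 lists. There 20 of the 24 genes of largest change were smaller by more than 1.5-fold, BMF at -0.97 among them, since the added offset of 50 shrinks changes of dim signals by construction. The margin between within- and between-group correlations was 0.0119 there and 0.00278 with no filter on dim probes.

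In the other 22 settings SEMA3F lay between -1.20 and -0.51 (adjusted p from 0.000145 to 0.0421) and CXCR4 between -1.83 and -1.07 (adjusted p from 4.16e-05 to 0.0414). Within slide 2, with 1 knockdown array, 2817 genes were called, 1084 higher and 1733 lower, where fewer samples leave less power. A fold of at least 2 left 2014 genes, 657 higher and 1357 lower. Spike-in scaling left 2172 genes higher, since it lowers the median of all genes by about the spike-ins' own difference. Lists past the threshold numbered 1 with the all-array filter, 1 with array weights, 6 with every probe on its own, 0 with an estimated correlation and 13 with fry. The cause was not tested. The FOXO list passed in each of the other 22 settings, and was lost with an estimated correlation. Of 104 other named genes, 0 changed sign in those of these 22 settings that gave them a value. Counting only the settings with a value, 75 passed in all and 91 in all except slide 2. With the filter on all 6 arrays only 82 of the 104 had a value, so the dimmer genes were not tried there. THY1, RPL13, DPP4, RGS5, TMEM150C and SDHA failed to pass in 13, 15, 14, 12, 10 and 8 of the 22 settings. A list called neither way in both settings was counted as unchanged.

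The replicate numbers gave no sign of pairing: same-numbered arrays' deviations from their group's mean correlated at -0.23, -0.088 and -0.047. No same-numbered arrays shared a slide, while knockdown 1 correlated with control 2 and control 3 on its slide at 0.098 and 0.13. Pairing can therefore not be told apart from slide here. With the replicate block 8061 genes were called and 1 list passed, and SEMA3F (-1.02) and CXCR4 (-1.65) kept their calls. Leaving out each array in turn gave 8177 to 10660 called genes, 1 to 3 lists, a correlation margin of 0.0140 to 0.0154, SEMA3F from -1.07 to -0.94 and CXCR4 from -1.73 to -1.56. ASCL2 was below background and has no main value to vary. With no filter its change was 0.39 by the brighter probe (SE 0.53, limma adjusted p = 0.617), while the second probe went the other way (-0.36). Signal over background limits the dim genes, and those above background on no array of a group have bounds only.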

Other observations

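The tests of slide and scan day, of cell division and of stromal cells were chosen after their results, or closely related ones, had been seen, as were the families by shared symbol below. The rules for reading the FOXO factor, copy number and cell division tests were tightened after their values were seen, and the example genes were chosen after theirs were seen. Among 222 families of at least 8 genes sharing a symbol stem, 22 passed (camera, adjusted over the families), and 0 did with an estimated correlation. Keratins stood first: of 35 tested, 27 rose and 1, KRT222, fell, with a median of 0.72 (adjusted p = 9.8e-07; adjusted p = 0.587 with an estimated correlation). KRT7 was at least 5.49-fold higher, KRT13 rose by 2.07 (values on 2 of 3 knockdown arrays) and KRT15 by 2.02, while KRT20, of differentiated intestinal epithelium, was at 0.25 (adjusted p = 0.554). Some members are pseudogenes or close copies whose probes may share signal, and the median was 0.54 with spike-in scaling and 0.84 with median centring.

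Some families of ribosome assembly and splicing also rose, while others did not pass (camera adjusted p = 0.0588 for NOL, 0.355 for PRPF and 0.723 for LSM). Of the RRP genes 8 of 9 rose (median 0.62, adjusted p = 0.0037), of the UTP genes 9 of 11 (median 0.67, adjusted p = 0.00889) and of the SRSF splicing factors 8 of 11 (median 0.83, adjusted p = 0.0045). Each was at adjusted p = 0.587 or above with an estimated correlation. Their medians stayed above 0 with median centring, spike-in scaling and quantile normalization. The stems RPS, MRPL and MRPS, mostly ribosomal proteins, also passed as higher (camera adjusted p = 0.0124, 0.00736 and 0.0215). With spike-in scaling, however, the medians of RPS, MRPL and MRPS were -0.0049, -0.0021 and -0.00083. Of 18 genes of intraflagellar transport, which builds cilia, 10 fell and 0 rose (median -0.29, adjusted p = 0.00736; adjusted p = 0.587 with an estimated correlation), among them IFT74 (-0.88) and IFT88 (-0.72). The median of these genes was -0.18 with median centring and -0.50 with spike-in scaling.

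The first pattern weighed was the number of changed genes. Slide and scan day as its whole source is argued against: of the genes called between slide 3 (knockdown 2 and 3) and slide 1 (control 1), 94.4% had the same sign within slide 2, in other arrays. Over all 22040 genes compared, the share was 80.6%. Knockdown 1 also correlated at 0.992 and 0.994 with the knockdown arrays of slide 3 against 0.976 and 0.978 with the controls on its own slide, though within slide 2 this rests on 1 knockdown array. Large copy number shifts between the 2 sorted populations as the whole source are argued against too. Of 546 windows of 25 neighbouring genes, 0.549% (exact 95% interval 0.113 to 1.6) shifted beyond the bound of the shuffled gene order. That is below the 5% this would need but not clear of the 1% set in advance, and a few regions stay open. The bound was a distance of 0.488 on the log2 scale from the median of the placed genes. Smaller copy number shifts would stay within it and are not excluded, and 4553 called genes changed by less than 0.5. The real split gave 10366 genes with complete values by limma against 0 in the highest of the other splits (at most 1403 at unadjusted p). Each other split mixes control and knockdown arrays, so the difference between the groups enters its spread and holds its calls down. Thus 1 of 10 splits gave as many, but 10 splits are too few for a share under 0.05, and no conclusion is drawn from them. Lower SEMA3F, other effects of the hairpin, the lentiviral integration and the sorting of each population are among the sources that stay open, untested. The comparison across slides does not cover differences in RNA amplification and labelling that follow the groups, which were not tested either. The control virus was empty, so effects of the hairpin on other transcripts cannot be told apart from those of lower SEMA3F.

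The second pattern was the fall of FOXO targets. A list chosen by luck is argued against by a second list of 14 tested FOXO targets and autophagy genes, whose median was -0.66 (camera p = 0.00051; p = 0.0209 with an estimated correlation), with 10 lower, such as ULK1 (-1.63) and GABARAPL1 (-1.44), and 2 higher, ULK2 (0.67) and ATG12 (0.55). Slower division of the control cells stays open. The DNA replication and mitosis list had a median of 0.0552 with an upper limit of 0.21, below the 0.3 that this would need. The limit was 0.32 with median centring, 0.063 with quantile normalization and 0.023 with spike-in scaling. It adds a multiple of the SE of the mean over the list's genes, taken as independent, and leaves out the spread between arrays. Lower FOXO factors stay open too: their median was -0.876, but FOXO3 rose. AKT activity was not measured, so no source in signalling was tested. Of 26 transcripts of its pathway, 5 rose and 9 fell. PIK3CA (-0.90), PIK3CD (-1.18) and RICTOR (-0.79), which act towards AKT activation, were lower, and the AKT phosphatase PHLPP2 (0.96) was higher. By themselves these changes would go with less AKT activity, whereas AKT represses FOXO targets, but transcript levels do not give activity.

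The third pattern was the rise of actin and contractility genes such as CNN1, ACTG2 and TAGLN. A few genes alone are argued against by 38 tested textbook targets of SRF and YAP outside the named genes and fixed lists, of which 31 rose, among them ZYX (1.92) and AMOTL2 (1.78), and 1 fell, with a median of 0.889 (camera p = 2.8e-10; p = 0.0074 with an estimated correlation). Fibroblasts, pericytes and muscle cells are argued against by 8 of their markers, though these were chosen after their or closely related results had been seen. Of the 8, 0 were above background on all knockdown arrays and called higher. COL3A1, DCN and LUM were above background on 0 arrays, and COL1A2 on 0 control arrays and 1 knockdown array. Of the 8, DES was above background on all arrays (-0.35) and PDGFRB on all control arrays (-0.85). THY1, a marker from the fixed list outside these 8, was above background on all arrays and called higher (0.19). Its call was lost with slide as a fixed block. Sorting on eGFP would also leave fibroblasts, pericytes and muscle cells out unless they were infected. Higher SRF and YAP activity in the knockdown cells stays a hypothesis, since the activity was not measured and the rise of their targets is part of the pattern itself.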
